A study of Schizosaccharomyces pombe with 5 samples.

How the data were processed

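H3K9me2 chromatin immunoprecipitation (ChIP) DNA from fission yeast was hybridised against input DNA on 5 tiling arrays, 1 array in each of 5 groups. The groups were growing wild type, the dcr1, sir2 and epe1 deletions, and nitrogen-starved wild type. Per the labels, cells grown at 30 °C were fixed in 3% paraformaldehyde, chromatin was sheared to between 500 and 1000 bp, and crosslinks were reversed at 65 °C. The antibody was raised against dimethylated histone H3 lysine 9 and sold by Abcam. ChIP DNA carried Cy5 and whole-cell extract DNA carried Cy3 after random-primed PCR. The title and condition label call 1 array nitrogen-starved, whereas its growth labels describe a growing culture, and the title was followed.

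Per the file headers, Agilent Feature Extraction 9.5.1.1 read the wild-type array and version 9.5.3.1 read the 3 deletion arrays. The submitters' own note names that tool without a version. The deposited processed signals are intensity values, background-subtracted, detrended in an additive and a multiplicative step, and dye-normalised with a linear factor, per the file headers. The deposited mean, median and background columns are raw intensity values. The deposited log ratio column is the log10 of Cy5 over Cy3 processed signal, which was tested on the values. The deposited columns on saturation, background and outliers are other values, namely flags of 0 or 1. The deposited value table holds a linear ratio of Cy5 over Cy3, times 1 constant per array. That constant came to -0.04 log2 for wild type, -0.03 for the dcr1 deletion, -0.03 for the sir2 deletion and 0.06 for the epe1 deletion, and its origin stays unknown. The table columns had medians of 0.966 in wild type, 0.964 in the dcr1 deletion, 0.990 in the sir2 deletion, 0.964 in the epe1 deletion and 0.947 in starved wild type. For the starved array no scanner file was analysed here, so its scale, centring and direction were read from the table alone, and its 2 channels could not be examined separately.

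The measure used throughout was the log2 ratio of Cy5 over Cy3 processed signal, centred on the median of each array, and the table ratio centred likewise for the starved array. Spots that the scanner software marked as outliers were left out on that array alone. They numbered 7274 of 41551 probes in wild type, 323 in the dcr1 deletion, 197 in the sir2 deletion and 605 in the epe1 deletion. Median signal over background in Cy3 was 493 in wild type, 351 in the dcr1 deletion, 384 in the sir2 deletion and 294 in the epe1 deletion. In Cy5 it was 58.9, 100.3, 130.3 and 49.2 in the same order. The number of arrays limits the precision.

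Probes were placed by exact match of their 60 bases in the ASM294v3 assembly, since the authors' build is not given in the sources used here. There were 40396 probes with 1 match, 1053 with several and 102 with none. Of the probes with none, 36 were assigned by their names to a separate mating-type contig, whose sequence was not searched. BLAST 2.17.0 with a word size of 11 found 1636 probes with another site of 40 or more identical bases, called near copies below. Median probe spacing was 300 bp.

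Constitutive regions were the pericentromeres (262 probes), the central cores of the centromeres (80), the silent mating-type region (207), the outer 50 kb of chromosomes I and II as subtelomeres (527), and the outer 20 kb of chromosome III (102). Central cores were probes within 5 kb of the midpoint of a fixed centromere interval, and pericentromeres those more than 8 kb from it. The mat2 gene is not annotated in the assembly, so the mating-type region was set as a stretch of 30 kb on chromosome II, from 2110075 to 2139847, plus the contig. A domain was a run of at least 3 probes with a running mean over 3 probes of at least 1 log2, joined across 1 probe below. An island was a domain at least 20 kb from any constitutive region. Differences were taken over probes measured on both arrays, so they can depart from the difference of 2 levels. A gene value was the mean over probes centred in the gene, and a gene was called enriched at 1 or more and called changed at a difference of 1 or more either way. Probes inside the deleted genes were left out of every level, island and ranking, along with the parts of neighbours that overlap them, a choice made after their high ratios had been seen. Each region and list value was compared with 10000 random sets of euchromatic windows or genes matched on number of probes and on quintile of Cy3 signal, which describes these arrays only. The regions, thresholds, lists, naming rule and the first set of other settings were fixed before the data were examined. Islands of at least 5 probes were among them. The subset at least 100 kb from constitutive regions without probes that have copies in them, and the zones of distance from chromosome ends and centromeres, were chosen after values were seen.

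The 10 fixed gene lists held 16 meiotic genes known as targets of the RNA-binding protein Mmi1, 4 other loci known as islands, 134 other genes with meiotic symbols, 24 mating and nitrogen-response genes, 3 phosphate genes, 2 subtelomeric helicase genes, 13 Tf2 retrotransposons, 25 wtf genes, 22 genes for heterochromatin, RNAi and RNA elimination factors, and 15 housekeeping genes. The Mmi1 list and the list of other islands were drawn in part from the study's own reports on these arrays, so their comparison with random lists is no independent test. Genes were named by 4 criteria. The first took any list member with at least 2 probes. The second took, for each comparison with wild type, the 10 largest rises and 10 largest falls among genes with at least 3 probes that lay more than 20 kb from constitutive regions, 1 gene per 10 kb neighbourhood. The third took the 5 largest rises and 5 largest falls inside those regions and their flanks of 20 kb. The fourth took genes in the 10 islands with the highest mean on each array.

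Each deletion and the starved array was compared with the wild-type array, and the dcr1 deletion with the sir2 deletion, which per the file names shared 1 slide. No test across arrays was possible with 1 array per group. Other settings chosen beforehand were normexp background correction with an offset of 50, loess within arrays, the deposited table, centring on the mode, a filter on dim probes, scaling to the mating-type region, domain thresholds of 0.6, 2 and 4 times the scaled median absolute deviation, domains of 5 probes, medians over probes, subtelomeres of 100 kb, an overlap of 50% for shared islands, genes with 500 bp added on each side, and raw signal for the deleted genes. Settings added after seeing the data kept outlier spots, used probes with 1 exact match, left out probes with near copies, used the ChIP channel alone for differences, called domains on a running median, and kept islands at least 100 kb from constitutive regions.

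The domain and gene steps were tested on simulated data drawn probe by probe from wild-type euchromatic values below 1 log2. Of 50 planted domains of 8 probes, 49 were found at a height of 1.5 log2, 50 at 2 and 50 at 3 under the rule of 3 probes. When at least 5 probes were required, 32 were found at 1.5, 44 at 2 and 50 at 3. Counts of islands of at least 5 probes can thus miss low domains. The 0 calls where none was planted were fixed in advance, because a running mean of values below 1 cannot reach 1. Neighbouring euchromatic probes correlated at 0.577 on the real wild-type array, so the simulation gives no rate of false calls. Of 50 genes shifted by 1 log2 upward, 50 passed 0.5 log2 in that direction, with a mean of 1.03. Of 50 shifted downward 49 did, with a mean of -0.99. Recovery at 1 log2, where a gene was called changed, was not counted, so these counts do not give its sensitivity. Among 4279 genes left in place, 180 passed 0.5 log2 either way. Of 400 random lists of 16 genes, 8.75% fell in the outer 10% of their random sets, and of 200 random stretches of 60 probes 12% did. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.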

Results

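The data were H3K9me2 profiles, the histone mark of heterochromatin, from Schizosaccharomyces pombe on 5 arrays. Growing wild type, strains lacking dcr1 (the RNAi enzyme Dicer), sir2 (a histone deacetylase) or epe1 (a JmjC-domain protein that opposes heterochromatin spreading), and nitrogen-starved wild type each had 1 array. There was no replicate check, so every ± below is an SD over probes, or over genes where a list is named, on 1 array. All differences from wild type share the same wild-type array. Values are median-centred log2 ratios of ChIP over input, and coordinates are those of ASM294v3. Input DNA was depleted by at least 4 log2 at 13 of 18 dcr1 probes on the dcr1 deletion array, at 6 of 8 sir2 probes on the sir2 deletion array and at 9 of 14 epe1 probes on the epe1 deletion array. No probe of these genes was depleted on the other scanned arrays, with counts of 0 throughout.

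The wild-type array addressed where H3K9me2 lies in growing cells. The pericentromeric repeats stood at 7.34 ± 2.59 (248 probes), the subtelomeres of chromosomes I and II at 5.95 ± 2.79 (514 probes) and the silent mating-type region at 4.36 ± 3.15 (203 probes). The ends of chromosome III stood at 3.98 ± 1.99 (102 probes) and the central cores of the centromeres at 2.29 ± 1.43 (76 probes). At the central cores the ChIP channel alone stood at -0.37 and the input channel at -2.54 against the array median. The ChIP signal there was thus not above the array median, and the input signal lay further below it. Input was also low at the central cores in the dcr1 (-2.29) and sir2 deletions (-2.08), where the ratios were 0.51 and 0.52. Low input alone thus does not give the wild-type ratio. Outside these regions the meiotic transcription factor gene mei4 (SPBC32H8.11, chromosome II, 1473068 to 1475285) stood at 6.44. The meiotic gene ssm4 (SPAC27D7.13C, chromosome I, 4534674 to 4536736) stood at 4.74, and mcp7 (SPAC13A11.03, chromosome I, 578450 to 579948), a meiotic coiled-coil protein gene, at 4.37. Without probes with near copies the pericentromeric level was 4.61, with loess the ends of chromosome III were at 0.83, and with normexp the central cores were at 1.13. With subtelomeres widened to 100 kb their level was 3.43.

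There were 99 islands in wild type, of which 45 rested on 1 high probe and 37 had at least 5 probes. Those 37 covered 131 kb with a median length of 2.73 kb. The highest islands without copies held mei4 with its neighbours cdk9 and act1 (mean 3.74), ssm4 (3.66) and mcp7 (3.26). The highest means of all were at mae2 (6.04), at ura4 (4.91), at SPBPB21E7.09 (4.64) and at mae1 (3.85), and mae1, mae2 and SPBPB21E7.09 share near copies with the subtelomeres. The island count was 23 at a threshold of 2 log2 and 186 at 0.6, and it was 40 with loess.

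Of the 16 Mmi1 target genes 5 were enriched in wild type, namely mei4, ssm4, mcp7, mug9 (SPCC70.09C) at 2.71 and num1 (SPBC216.02, also known as mcp5) at 2.62. The list median was 0.30, above the 95% interval of random lists (-0.14 to 0.05), which is not independent evidence because part of the list came from the study. Of 4 other known islands 3 were enriched, namely the vacuolar sorting gene vps29 at 3.22, SPAC8C9.04 at 2.46 and the MADS-box gene mbx2 at 1.81, while rmr1 stood at 0.02. Among 123 other meiotic genes 2 were enriched, meu27 (2.68) and meu1 (1.64), both within 20 kb of a centromere. Of 23 mating and nitrogen-response genes 1 was enriched, isp5 (1.31). Of 3 phosphate genes 1 was, the acid phosphatase gene pho1 (1.17). The subtelomeric helicase gene tlh1, whose probes are shared with other subtelomeric copies, stood at 8.76. Of 10 Tf2 elements, which share probes, 6 passed 1 with a median of 1.02, which was -0.22 with normexp and -3.53 with loess. None of 24 wtf genes, which also share probes, passed 1 (count 0, median 0.36, and -0.45 with normexp). None of 19 genes for heterochromatin factors did (count 0, median -0.01). Of 15 housekeeping genes 2 did, act1 (1.65) beside mei4 and rpb1 (1.85) beside a centromere.

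**Figure D1:**
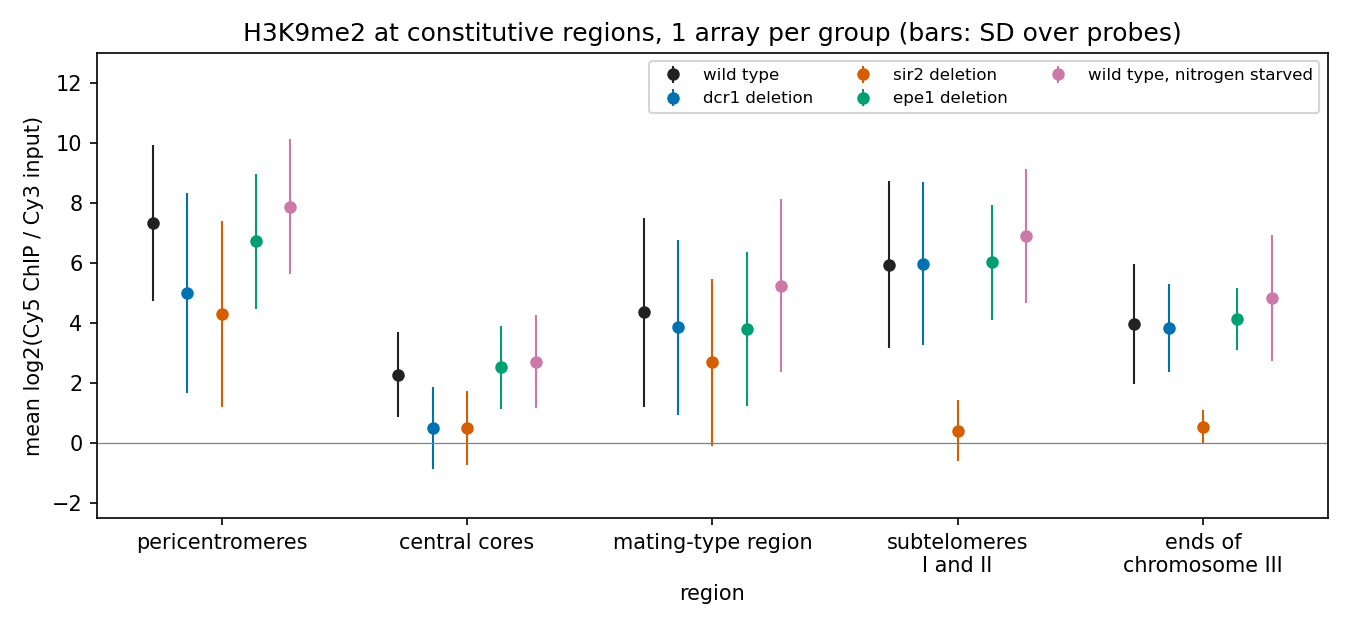
Mean log2 ratio of ChIP over input (vertical axis) in 5 constitutive regions (horizontal axis), with 1 point per array and bars for the SD over probes. The sir2 deletion lies at 0.42 in the subtelomeres, where the 4 other arrays lie between 5.95 and 6.90.

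The dcr1 deletion against wild type asked how far H3K9me2 needs RNA interference. H3K9me2 fell by 2.31 ± 1.66 at the pericentromeres (230 probes, 4.95-fold lower) and fell by 1.68 ± 1.13 at the central cores (75 probes). The subtelomeres differed by 0.08 ± 0.62 (498 probes) and the ends of chromosome III by -0.14 ± 0.74 (102 probes). The islands at meiotic genes were lower and largely still present, with mei4 at 4.13 after a fall of 2.31 log2 (difference -2.31 ± 0.19, 7 probes). Zones within 10 kb outside the centromeres went from 2.01 in wild type to 0.07 on chromosome I, from 2.45 to 0.36 on chromosome III and from 1.43 to 0.95 on chromosome II.

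In the ChIP channel alone the pericentromeric difference was -1.71, and the input channel was higher by 0.63 than in wild type. With loess the pericentromeric difference was -1.38, and those at the subtelomeres and the ends of chromosome III were 0.87 and 0.86. Without near copies the central core difference was -0.94. Within the mating-type region the difference was -0.39 ± 0.38 (199 probes), and it was 0.26 with loess. The pericentromeric level left in the dcr1 deletion, 5.0 ± 3.34, was 1.29 without probes with near copies. Of the 16 Mmi1 genes 5 fell by 1 or more. Beside mei4 these were ssm4 (-2.37 ± 0.35), mug9 (-2.03 ± 0.27), mcp7 (-1.43 ± 0.24) and num1 (-1.13 ± 0.22), and ssm4 (2.37), mcp7 (2.94) and num1 (1.41) stayed above 1 while mug9 was at 0.68. With mei4 and mug45 (1.18) they made 5 enriched genes of 16. The list median difference was -0.16. With loess the differences were -0.85 at mei4, -1.0 at ssm4, -0.92 at mcp7 and -0.51 at num1. Among the 4 other known islands vps29 fell by 2.79 ± 0.02 (3 probes), and its difference was -1.77 with loess. The other 3 differed by -0.47 (mbx2), -0.50 (SPAC8C9.04, 0.02 with loess) and 0.27 (rmr1). The gene vps29 lies 20 to 50 kb outside the centromere of chromosome I. Over that zone of all centromeres the mean went from 0.97 in wild type to 0.19 in the dcr1 deletion and 0.16 in the sir2 deletion.

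Of 4139 genes more than 20 kb from constitutive regions 33 fell by 1 or more and 0 rose that much. The deepest fall was at ura4 (SPCC330.05C, chromosome III, 115589 to 116625), a uracil synthesis gene widely used as a marker, which stood at 8.39 in wild type on 4 probes and at 0.76 in the dcr1 deletion on 3. The difference over the 3 probes measured on both arrays was -7.82 ± 0.16. Near the centromeres tum1 (-1.72), SPAC4H3.01 (-1.45) and nro1 (-1.37, or -0.66 with loess) fell. The largest differences upward among these genes were at erp2 (0.93 ± 0.74) and slx9 (0.88 ± 1.32), neither past 1. Inside the regions and their flanks of 20 kb emc5 (-5.47), per1 (-3.72), ppc1 (-3.10), meu27 (-2.24) and cbs2 (-2.11) fell, all beside centromeres. There SPAC977.05C (2.41, 3 of 3 probes with near copies), the flocculin gene pfl9 (1.69, or 0.95 in the ChIP channel alone), SPCP20C8.02C (1.04) and SPCC569.01C (1.02) rose, these last also on probes with near copies. In the remaining lists 2 meiotic genes fell, meu27 and meu1 (-1.73), and no mating gene, phosphate gene, Tf2, wtf, heterochromatin factor or housekeeping gene passed 1 either way (counts of 0). Phosphate genes had a median difference of 0.42, and tlh1 differed by -0.20, or 0.90 after mating-type scaling.

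Island calls numbered 113 in the dcr1 deletion, of which 71 rested on 1 high probe and 29 had at least 5 probes. Of the 37 wild-type islands of that length 34 were lower and 10 were lower by 1 or more. These islands were picked as high on the wild-type array, so lower values on another array were favoured in advance. In the dcr1 deletion 20 of the 37 had a mean of 1 or more and 17 fell below it, as did 16 of the 22 within 100 kb of constitutive regions. Of the 10 that lay farther away and had no probe with a copy in those regions, a subset chosen after values were seen, 9 had a mean of 1 or more.

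The sir2 deletion against wild type asked what H3K9me2 needs this deacetylase. H3K9me2 at the subtelomeres fell by 5.54 ± 2.62 (514 probes, 46.6-fold lower), to 0.42, and the difference was -3.80 in the ChIP channel alone, with the input channel higher by 1.76. At the ends of chromosome III it fell by 3.42 ± 1.60 (102 probes), at the pericentromeres by 2.39 ± 1.16 (183 probes, difference -2.39), and at the central cores by 1.79 ± 0.67 (76 probes, difference -1.79). At the mating-type region it fell by 1.55 ± 0.84 (200 probes). Removal of outlier spots left 187 of 262 pericentromeric probes on the sir2 deletion array. Wild type stood at 6.64 over the 183 pericentromeric probes compared and at 7.34 over its own 248, so higher probes were left out. All wild-type islands of at least 5 probes were lower than in wild type (37 of 37). That direction was favoured in advance, because the islands were picked as high in wild type. The gene mei4 fell by 5.40 ± 0.34, to 1.04.

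In the ChIP channel alone the difference at the ends of chromosome III was -1.51, with loess it was -1.11 there, -0.76 at the pericentromeres and -0.52 at the mating-type region, and with subtelomeres of 100 kb the subtelomeric difference was -3.31. Scaling to the mating-type region turned the pericentromeric difference to 0.24, whereas it left the subtelomeric fall. Of the 16 Mmi1 genes 5 fell by 1 or more, with mcp7 (-4.60 ± 0.43), ssm4 (-4.44 ± 0.65), mug9 (-2.64 ± 0.64) and num1 (-2.47 ± 0.75) beside mei4. Only mei4 stayed enriched in that list, 1 gene of 16, and with loess or with flanks added 0 did. The list median difference was -0.26. With loess mei4 differed by -2.98 and ssm4 by -2.72. Of the 4 other known islands 3 fell, vps29 (-2.71 ± 0.38, and -1.68 with loess), SPAC8C9.04 (-2.37 ± 0.90, and -1.08 with loess) and mbx2 (-1.71, and -0.99 with loess).

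More than 20 kb from constitutive regions 54 of 4141 genes fell by 1 or more and 1 rose, slx9 (1.02 ± 1.28, 3 probes, and 0.53 with flanks added). The deepest falls were at mae2 (-7.71 ± 0.41), SPBPB21E7.09 (-7.50 ± 0.18), mei4 (-5.40, without near copies) and mae1 (-5.08 ± 3.62). Probes of mae2, SPBPB21E7.09 and mae1 share near copies with the subtelomeres, and mae1 differed by -2.19 without such probes. The gene ura4 was not among the 10 deepest falls and still stood at 6.83. Inside the regions and their flanks SPAC212.08C (-8.81), SPAC186.07C (-8.65), SPBC1348.05 (-7.40), SPAC186.02C (-7.37) and SPAC977.14C (-7.27) fell, each with 1 or more probes with near copies, the last in the flank of a subtelomere and the others inside subtelomeres. The helicase gene tlh1, with shared probes, fell by 6.15, to 2.77 (-6.15, and -2.71 in the ChIP channel alone). Further falls past 1 were at pho1 (-1.23), at meu27 (-1.84) and meu1 (-1.51), and at the housekeeping genes act1 (-1.71) and rpb1 (-1.02). No mating gene, Tf2, wtf or heterochromatin factor gene passed 1 (counts of 0), and mating and nitrogen-response genes had a median difference of -0.14.

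Of 64 islands called in the sir2 deletion 57 rested on 1 high probe and 3 had at least 5 probes, at ura4, at pfl2 and at SPBPJ4664.02. After mating-type scaling the count was 135.

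The dcr1 deletion against the sir2 deletion compared the arrays that shared 1 slide. The subtelomeres stood 5.60 ± 2.62 higher in the dcr1 deletion (508 probes, 48.4-fold), the ends of chromosome III 3.28 ± 1.04 higher (102 probes) and the mating-type region 1.19 ± 0.76 higher (200 probes). The pericentromeres differed by -0.20 ± 0.96 (178 probes) and the central cores by 0.08 ± 0.95 (77 probes). The first lay below its random interval (-0.05 to 0.30) and the second within its own (-0.09 to 0.57). Of the 16 Mmi1 genes 4 stood higher in the dcr1 deletion by 1 or more, mcp7 (3.18), mei4 (3.09), ssm4 (2.07) and num1 (1.28). Among other lists pho1 (1.74), SPAC8C9.04 (1.78), mbx2 (1.24) and tlh1 (5.82) did. Mating-type scaling made the pericentromeric difference -2.23, and in the ChIP channel alone the subtelomeres differed by 3.68 and the ends of chromosome III by 1.35. More than 20 kb from constitutive regions 33 of 4470 genes were higher and 1 lower by 1 or more, the lower 1 being ura4 at -6.17 ± 0.25.

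**Figure D2:**
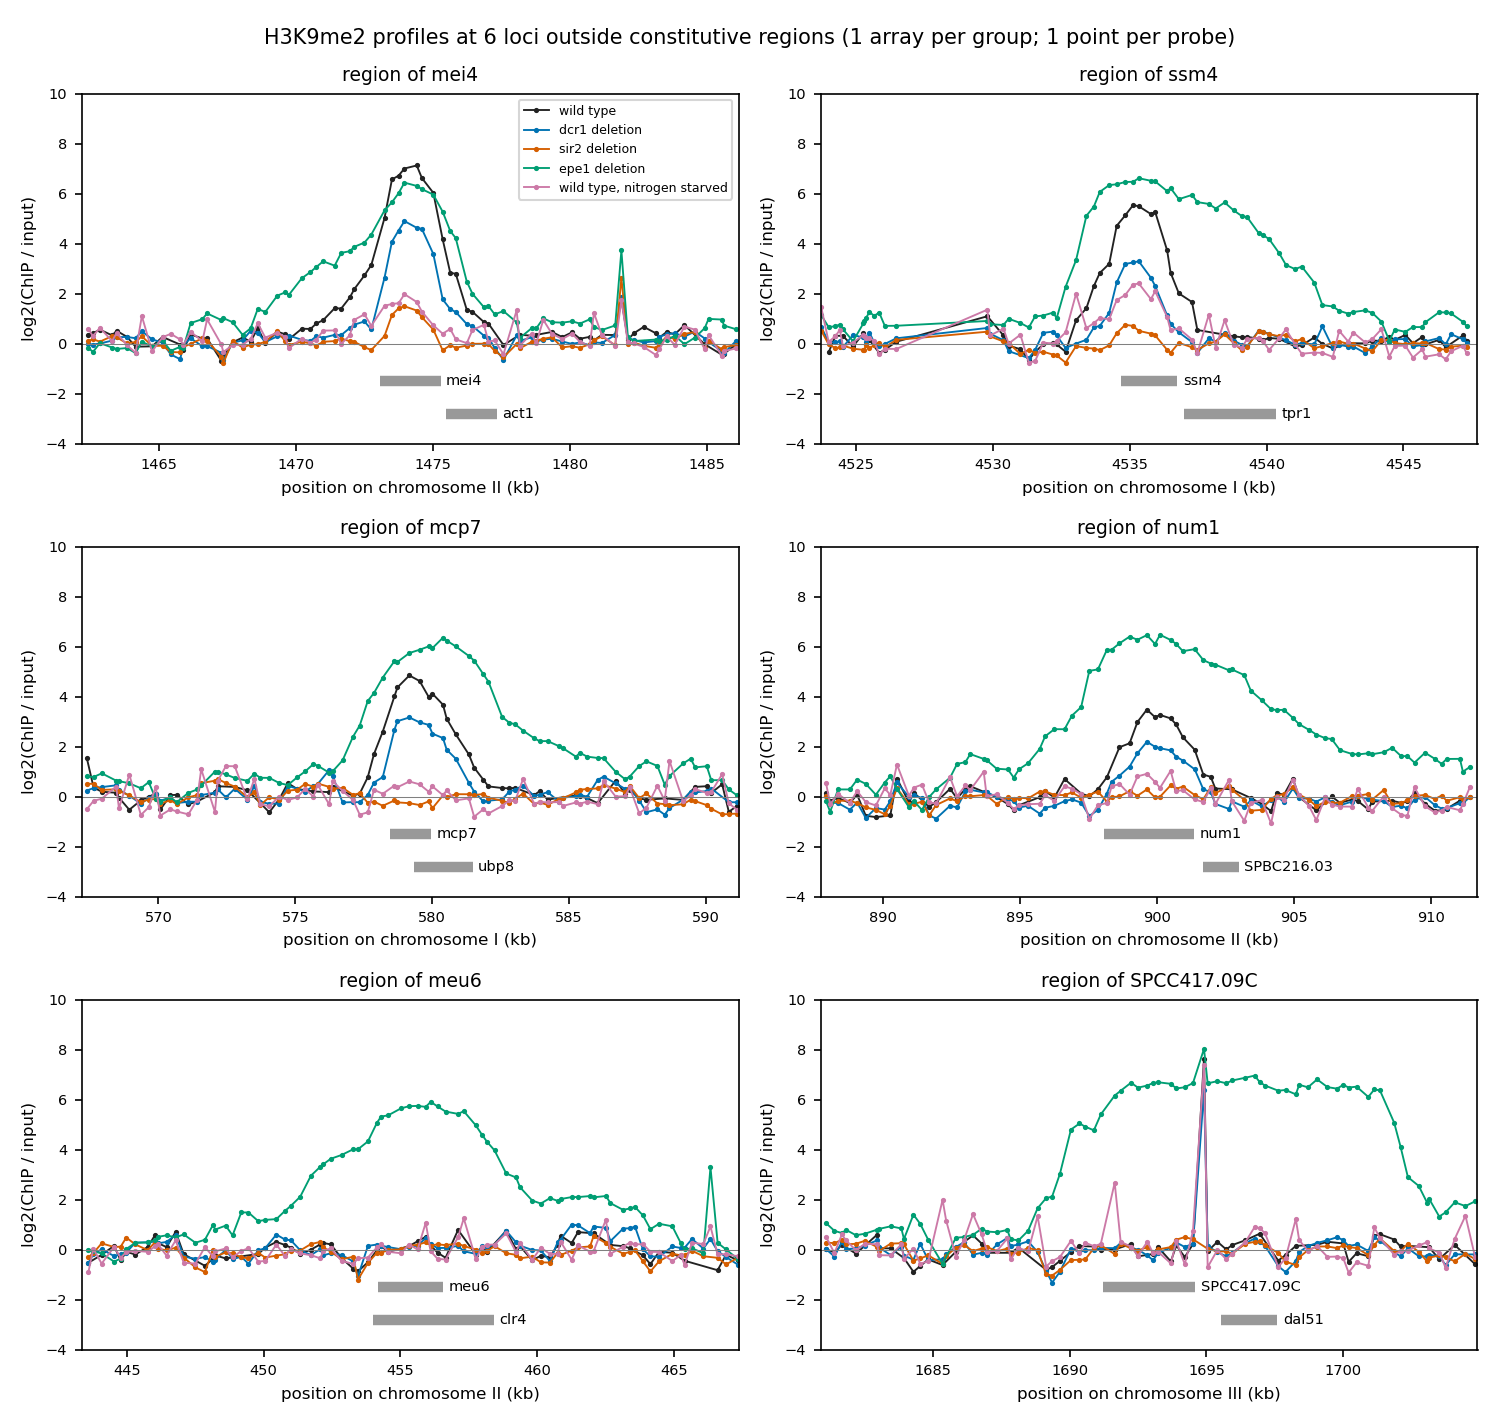
Log2 ratio of ChIP over input (vertical axis) against chromosome position in kb (horizontal axis) around 6 loci, with 1 line per array, 1 point per probe and grey bars for genes. At mei4 the gene means ran from 6.44 in wild type to 1.04 in the sir2 deletion and 1.48 under starvation, and at meu6 the epe1 deletion stood at 5.64 against 0.15 in wild type.

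The epe1 deletion against wild type asked where Epe1 limits H3K9me2. Per the file names these arrays lay on different slides, so the deletion and the slide cannot be told apart here. Island calls numbered 229 against 99 in wild type, and those of at least 5 probes numbered 79 against 37 and covered 428 kb against 131 kb. With the threshold scaled to the spread of log2 ratios on each array, at 4 median absolute deviations, the order turned, with 40 against 54. That scaled spread was 0.547 in the epe1 deletion and 0.370 in wild type. Neighbouring euchromatic probes correlated at 0.753 and 0.577, so the spread is not probe noise alone. More than 20 kb from constitutive regions H3K9me2 rose most at SPCC417.09C (from -0.06 to 6.53, 6.60 ± 0.30, 9 probes) and at meu6 (SPBC428.07), a meiotic gene (from 0.15 to 5.64, 5.49 ± 0.26, 7 probes). The meu6 probes lie within the annotated span of clr4, the H3K9 methyltransferase gene, whose own mean rose from 0.10 to 5.37 (5.24). At the existing island of num1 the level rose from 2.62 to 6.16 (3.57), which turned to -0.41 with loess. Region averages differed by -0.70 ± 0.49 at the pericentromeres (248 probes) and 0.05 ± 1.22 at the subtelomeres (514 probes). Of 52 genes inside constitutive regions 6 rose and 12 fell by 1 or more, so such averages can hide changes both ways.

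The central cores differed by 0.20 ± 0.61, the mating-type region by -0.51 ± 0.75 and the ends of chromosome III by 0.16 ± 2.83. With loess the pericentromeres differed by -3.88, the mating-type region by -1.99 and the subtelomeres by -2.44, and the pericentromeric difference was 0.48 in the ChIP channel alone and 0.27 after mating-type scaling. The island count was 122 with loess against 40 in wild type.

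Rises at islands depended on the within-array normalisation. With loess they were -1.20 at ssm4, -1.02 at mcp7 and -0.56 at mbx2, and 1.96 at SPCC417.09C, 1.03 at meu6 and 1.36 at clr4. Loess also took the pericentromeres of the epe1 deletion from 6.72 to 1.40 and its subtelomeres from 6.03 to 1.60. Lower values under loess were thus not particular to islands on that array. Of the 16 Mmi1 genes 6 rose by 1 or more and 0 fell, with mug9 (1.83, or 0.91 in the ChIP channel alone), tht2 (1.71), ssm4 (1.67) and mcp7 (1.32) beside meu6 and num1. The list median difference was 0.47, and 9 genes were enriched. The gene mei4 differed by -0.46 and turned to 0.42 after mating-type scaling, 0.08 with flanks added and 0.29 in the ChIP channel alone. Of the 4 other known islands 1 rose, mbx2 (1.09), and vps29 differed by -0.93. Of 122 other meiotic genes 5 rose, meu19 (2.42, with near copies), mug105 (1.91), meu29 (1.22), mug27 (1.16) and mug170 (1.03). Of 23 mating genes 3 did, gpa1 (1.37), isp3 (1.06) and rep1 (1.05), and of 3 phosphate genes 2 did, pho1 (2.07, or 1.29 with loess) and tgp1 (1.01, or 0.63 with loess). Of the housekeeping genes act1 rose (1.04). Tf2 elements, which share probes, had a median difference of 0.65 and -2.69 with loess, and wtf genes one of 0.00 and -1.53 with loess.

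Of 4122 genes more than 20 kb from constitutive regions 115 rose by 1 or more and 9 fell. Further large rises were at SPAPJ695.02 (5.37), SPBC216.03 (4.71), SPBC1289.14 (4.61), tpr1 (4.56), tmp1 (4.13), SPBC337.02C (3.98, or 2.40 without near copies), ddr48 (3.66) and erm1 (3.45). With loess SPAPJ695.02 was at 2.27, SPBC216.03 at 0.99, SPBC1289.14 at 1.39, tpr1 at 0.56, SPBC337.02C at 1.19 and erm1 at 0.26. Inside constitutive regions and flanks dak2, a dihydroxyacetone kinase gene (6.50, or 2.37 with loess), SPCC569.05C (6.04, or 3.51), SPCP20C8.02C (5.57, or 2.86), SPAC977.05C (3.30, or 0.05) and fex2 (3.10, or 1.74 without near copies) rose, all but dak2 with 3 or more probes with near copies. The falls past 1 were small, with rpl35 (-1.19) and pef1 (-1.08) among them. At ura4 (-1.17), mae2 (-1.10), SPBPB21E7.09 (-1.07), SPAC212.08C (-1.52) and pdc102 (-1.40) the ChIP channel alone gave 0.48, 0.36, 0.29, 0.29 and 0.14 in that order. The falls at mat3-Mc (-1.80) and mat1-Mc (-1.69), which share probes, were -0.43 and -0.11 there, that at SPAC186.02C (-1.38) was -0.61 and that at tlh1 (-1.22) was 0.51.

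Of the 79 epe1 deletion islands of at least 5 probes 38 overlapped a wild-type domain and 41 overlapped none. Among those at least 100 kb from constitutive regions 20 overlapped 1, of which 19 were longer than in wild type, with median lengths of 7.18 kb against 2.72 kb. These islands were picked for at least 5 probes in the epe1 deletion, and the wild-type domains needed only 3. Greater length in the epe1 deletion was thus favoured in advance. The islands include mae1 and mae2, with near copies in the subtelomeres, and several Tf2 elements, which share probes. The longest far islands were 17.4 kb from tef3 over SPCC417.09C and dal51, 17.3 kb over gpa2 and avl9, 16.5 kb over num1, 15.9 kb from fap2 to tht2 and 15.3 kb over clr4 and meu6. These 5 were singled out after their values were seen. At chromosome ends, the zone from 50 to 75 kb at the left end of chromosome I stood at 5.96 ± 1.56 in the epe1 deletion and 1.64 ± 1.54 in wild type. The zone from 20 to 30 kb at the right end of chromosome III stood at 5.66 ± 0.81 and 0.18 ± 0.64. Other ends differed less or not at all. From 50 to 75 kb the right end of chromosome I stood at 2.79 in the epe1 deletion and 2.77 in wild type, the left end of chromosome II at 1.75 and 0.74 and its right end at 3.08 and 1.82, and from 20 to 30 kb the left end of chromosome III stood at 4.81 ± 1.55 and 1.93 ± 1.98.

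**Figure D3:**
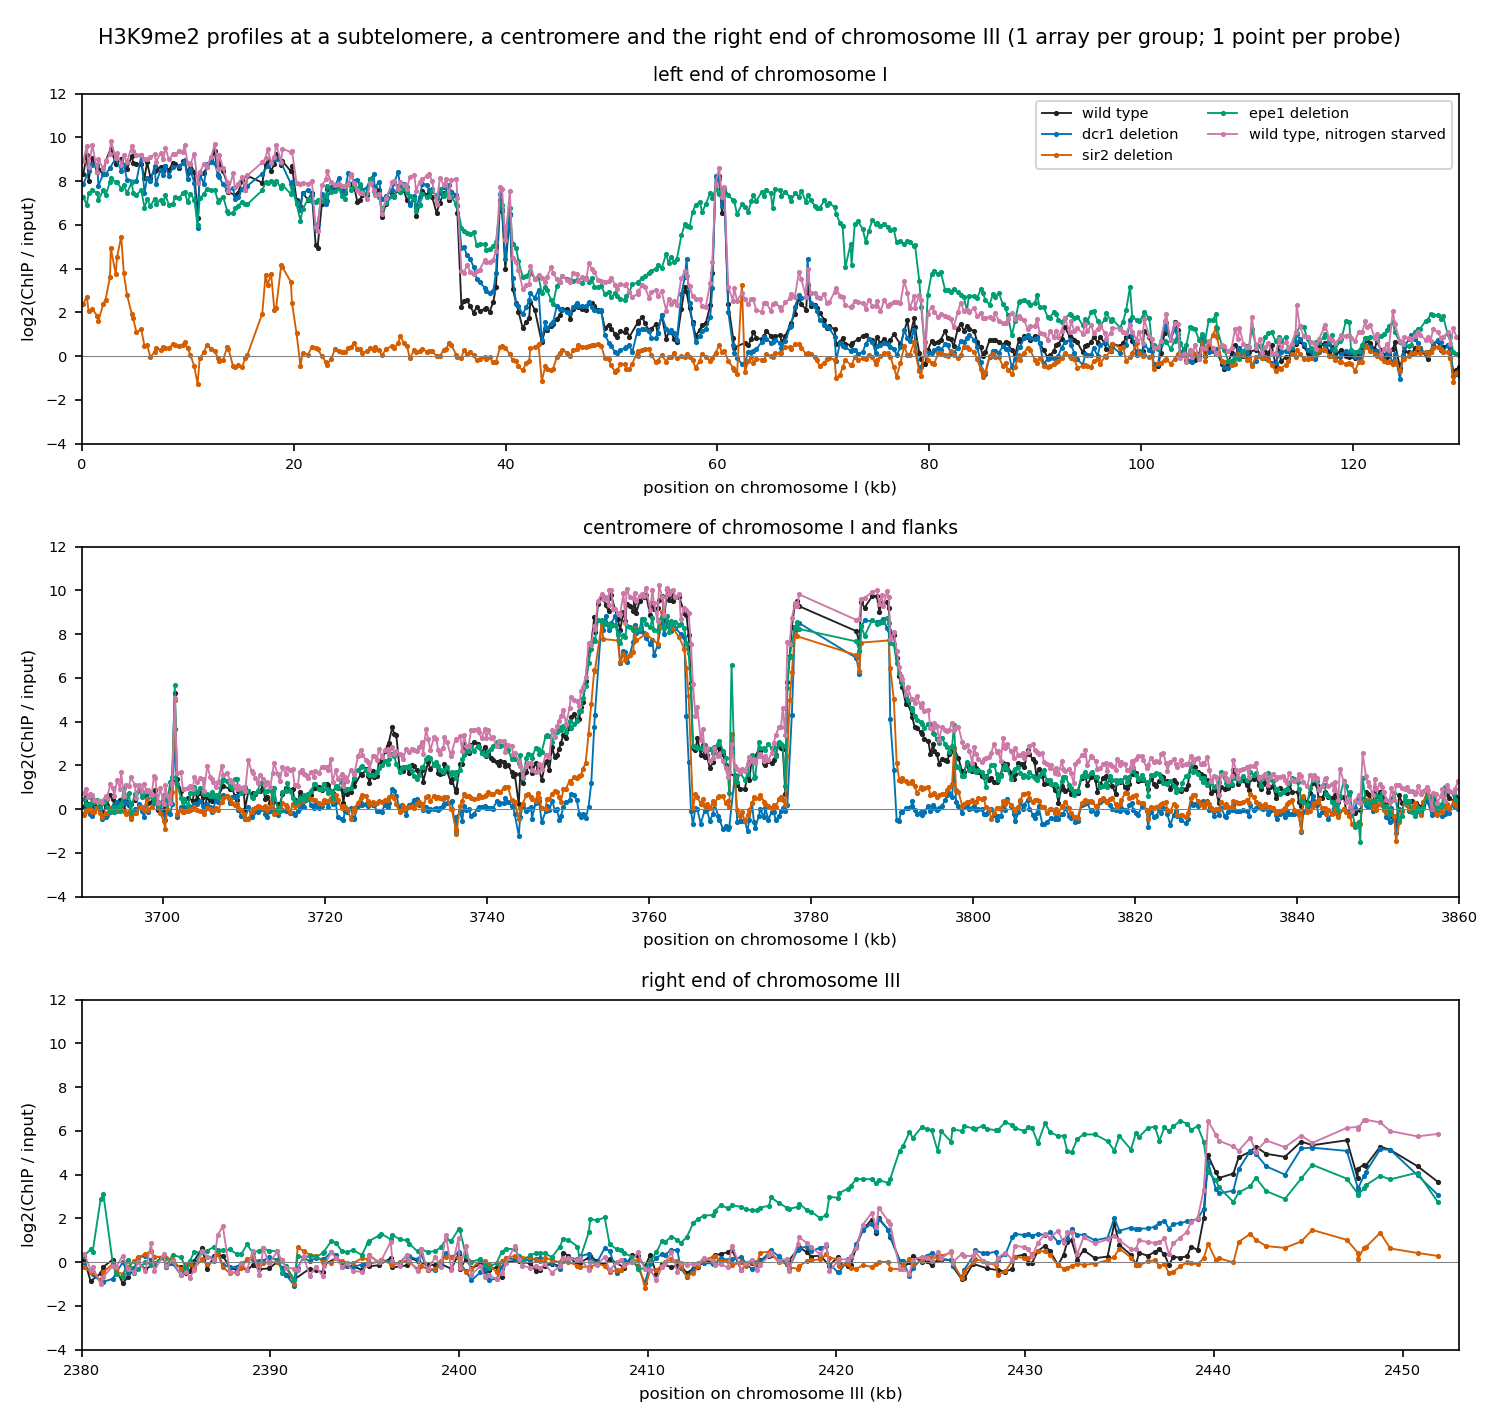
Log2 ratio of ChIP over input (vertical axis) against chromosome position in kb (horizontal axis) at the left end of chromosome I, the centromere of chromosome I and the right end of chromosome III, with 1 line per array and 1 point per probe. From 50 to 75 kb at the left end of chromosome I the epe1 deletion had a mean of 5.96 and the sir2 deletion one of -0.08.

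The nitrogen-starved array against growing wild type asked what becomes of H3K9me2 at meiotic genes when cells prepare for mating. Levels at the meiotic islands fell, by 4.96 ± 0.66 at mei4 (to 1.48), by 3.95 ± 0.27 at mcp7 (to 0.42), by 3.00 ± 0.38 at ssm4 (to 1.74), by 2.57 ± 0.31 at mug9 (to 0.14) and by 2.17 ± 0.57 at num1 (to 0.44). The constitutive regions did not fall, with differences of 0.49 ± 0.65 at the pericentromeres (248 probes), 0.93 ± 0.45 at the mating-type region (203 probes), 0.92 ± 0.72 at the subtelomeres (514 probes), 0.87 ± 0.71 at the ends of chromosome III (102 probes) and 0.46 ± 0.58 at the central cores (76 probes). After mating-type scaling the subtelomeres differed by -0.23, the pericentromeres by -0.83 and the ends of chromosome III by 0.06.

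Of the 16 Mmi1 genes 5 fell by 1 or more and 0 rose, with a list median difference of -0.61, and meu6 differed by -0.02. Of the 4 other known islands 2 fell, SPAC8C9.04 (-1.76 ± 0.82) and mbx2 (-1.69 ± 0.59), and vps29 differed by -0.55. Of 4147 genes more than 20 kb from constitutive regions 15 fell by 1 or more, and other falls among them were at iec1 (-1.60), avl9 (-1.38) and cbh1 (-1.12 ± 1.95, or -0.64 with flanks added). There were 23 rises among these genes, led by SPBPB10D8.02C (1.71), SPAPJ695.02 (1.64), alr2 (1.59) and SPAC869.09 (1.59, or 1.04 after scaling), all near chromosome ends, and SPBC1711.15C (1.57) and nup85 (1.16) near the mating-type region. Inside the regions and flanks SPBC1348.12 (1.88), yhb1 (1.86, or 1.06 after scaling), mtd1 (1.67, or 1.10), fex2 (1.64) and ayr2 (1.62, or 1.03) rose, fex2 and ayr2 on probes with near copies. In other lists meu27 (1.32), meu1 (1.12), the meiosis inducer gene mei3 (1.01) and rpb1 (1.40) rose and act1 fell by 1.29. No phosphate gene, Tf2, wtf or heterochromatin factor gene passed 1 (counts of 0), and tlh1, with shared probes, differed by 0.35, or -1.18 after scaling. Island calls numbered 161, of which 83 rested on 1 high probe and 51 had at least 5 probes. Of the 37 wild-type islands of that length 25 were higher and 12 lower, 10 of them by 1 or more, with a median difference of 0.41. Lower values were favoured in advance, because these islands were picked as high in wild type. Of the 22 within 100 kb of constitutive regions 19 were higher. Of the 10 farther away and without copies in those regions, a subset chosen after values were seen, 8 were lower by 1 or more. No scanner file of this array was analysed here, so its channels could not be read apart, and its growth labels describe a growing culture.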

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

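All tests in this part were chosen after the values they measure had been seen. Probes without a match in the reference that came from subtelomeric clones (62 probes) lay outside the main regions and stood above random windows on each array. They stood at 4.87 in wild type, 4.03 in the dcr1 deletion, 0.68 in the sir2 deletion, 4.17 in the epe1 deletion and 6.50 in starved wild type, where random windows reached 0.67, 0.38, 0.16, 1.41 and 1.13 in that order. Mitochondrial probes (58 probes) stood at 0.63 in the sir2 deletion, above a random limit of 0.17, and at 0.23 or lower on the other arrays, within their limits. The input channel alone, in Cy3, stood at 0.46 in the subtelomeres and 2.18 at the ends of chromosome III in the sir2 deletion, above a random limit of 0.30. In wild type the same input values were -1.30 and 0.27. The input channel thus carries part of the sir2 ratio difference at these ends, and the ChIP channel alone gave -1.51 at the ends of chromosome III. Input also departed from the array median elsewhere on other arrays. In wild type it stood at -1.77 in the pericentromeres, and at ura4 it stood at -1.99 against 0.33 in the dcr1 deletion. Ratio differences there can thus exceed those of the ChIP channel. No biological explanation was tested for these values.

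The first pattern weighed was the lower pericentromeric level in the dcr1 and sir2 deletions, whose arrays shared a slide that wild type did not. A slide or scan that compresses every ratio would lower the subtelomeres of the dcr1 deletion too, but they differed by 0.080 ± 0.62 against -2.31 at the pericentromeres. In the sir2 deletion such compression stays open for the pericentromeres, since the mating-type contig, high on all 5 arrays, differed by -2.15 ± 0.88 against -2.39. An effect of each deletion on the pericentromeres also stays open as untested by any second array.

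The second pattern was ura4, above 6 on each array but that of the dcr1 deletion. Of its 4 probes 0 had a near copy in the reference, and the arrays that shared a slide differed there by -6.17 ± 0.25, so neither near copies nor the slide accounts for it. A candidate explanation is a strain difference, in which strains other than the dcr1 deletion carry a ura4 copy inside a heterochromatic region. Of 12 probes 1 to 3 kb outside ura4 measured in wild type, the 11 without near copies stood at 0.73 or lower, as such a copy would give. The remaining probe, which has a near copy, stood at 3.60 in wild type and at 3.62 in the dcr1 deletion, so it did not follow ura4. Under 1 kb outside, wild-type probes ran up to 8.68, and in the epe1 deletion probes without near copies 1 to 3 kb outside reached 1.43, so such a copy stays open and was not shown. An effect of the dcr1 deletion on ura4 chromatin stays open, and the genotype labels were not enough to tell.

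The third pattern was wild-type islands whose probes have copies elsewhere. At mae1, mae2 and SPBPB21E7.09 wild-type probes with near copies had a mean of 8.01 ± 0.45 (12 probes). Those without had 2.22 ± 2.64 (2 probes), too few to tell pairing with subtelomeric DNA from H3K9me2 at the genes. On 4 probes without near copies the means were 1.20 ± 1.68 (dcr1 deletion), 1.36 ± 1.47 (epe1 deletion) and 1.76 ± 1.93 (starved). With near copies they were 8.12, 6.89 and 8.39 in that order. In the sir2 deletion both kinds were low, at -0.06 and 0.32. The wide SDs leave the question open. Of 45 islands that rest on 1 probe 18, or 40%, had a near copy in a constitutive region at that probe, against 0.176% of background probes, so copies in those regions may account for those. Near copies outside those regions were found for 2 more and stay open there. The other 25 had none, and for these a short sequence shared by the probes stays open. The 8-base word picked on chromosome I was in only 1 of 12 probes there, so its share of 0% among 13 probes on chromosomes II and III decides nothing. No biological explanation was tested for islands on 1 probe.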

How the results depend on the processing

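The 6 last settings of this part, from outlier spots kept to islands beyond 100 kb, were chosen after the results were seen. So was the way a change of direction was counted, namely for any value past 1 log2 or past its own SD. Across all settings run, the pericentromeric difference of the dcr1 deletion stayed below zero (-3.32 to -1.38), as did the subtelomeric difference of the sir2 deletion (-6.79 to -3.31), its difference at the ends of chromosome III (-4.09 to -1.11) and the central core differences of the dcr1 (-1.72 to -0.94) and sir2 deletions (-1.87 to -1.22). The pericentromeric difference of the sir2 deletion ranged from -2.84 to 0.24 and changed direction with mating-type scaling, which makes that region the reference. The mating-type differences after this scaling are near 0 by construction and check nothing about that region. The deposited table, the filter on dim probes, medians over probes and the 50% overlap moved 0 values past these limits, and the table differs from the scanner values by 1 constant per array. Of the named gene differences, loess moved 66 without a change of direction, and mating-type scaling moved 61. Centring on the mode shifted the epe1 deletion by 0.13 and the starved array by 0.15 log2. Signal over background in Cy5 was 58.9 in wild type and 49.2 in the epe1 deletion against 130.3 in the sir2 deletion, which limits differences between low levels. The starved array has no value under normexp, loess, the dim-probe filter or the ChIP channel, which need scanner files. No paired analysis was possible because each group had 1 array. The values below are those that moved by more than their spread, or counts by more than 1.5 times, and the cause was not tested except where a setting removes the probes or domains counted.

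With normexp the pericentromere difference was 0.065 (epe1 deletion). The central core level was 1.06 (epe1 deletion). The chromosome III end level was -0.066 (sir2 deletion). Island counts were 71 (dcr1 deletion). Enriched other meiotic genes numbered 2 (dcr1 deletion) and 1 (sir2 deletion). Enriched mating and nitrogen genes numbered 0 (wild type) and 3 (epe1 deletion). The tlh1 levels were 8.03 (wild type) and 7.75 (dcr1 deletion). The tlh1 difference was -0.41 (epe1 deletion). Enriched Tf2 elements numbered 0 (wild type), 0 (dcr1 deletion), 0 (sir2 deletion) and 0 (epe1 deletion). The Tf2 median levels were -0.22 (wild type), -0.35 (dcr1 deletion), 0.062 (sir2 deletion) and 0.35 (epe1 deletion). The Tf2 median differences were 0.28 (sir2 deletion) and -0.40 (dcr1 against sir2 deletion). The wtf median levels were -0.45 (wild type), -0.41 (dcr1 deletion), 0.028 (sir2 deletion) and -0.57 (epe1 deletion). The wtf median differences were 0.46 (sir2 deletion) and -0.41 (dcr1 against sir2 deletion).

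Under loess the pericentromere level was 1.40 (epe1 deletion). The pericentromere differences were -0.76 (sir2 deletion) and -3.88 (epe1 deletion). The mating-type level was 1.09 (epe1 deletion). The mating-type differences were 0.26 (dcr1 deletion), -0.52 (sir2 deletion) and -1.99 (epe1 deletion). The subtelomere level was 1.60 (epe1 deletion). The subtelomere differences were 0.87 (dcr1 deletion) and -2.44 (epe1 deletion). The chromosome III end levels were 0.83 (wild type), 1.69 (dcr1 deletion), -0.27 (sir2 deletion) and 0.38 (epe1 deletion). The chromosome III end differences were 0.86 (dcr1 deletion), -1.11 (sir2 deletion) and 1.97 (dcr1 against sir2 deletion). Island counts were 40 (wild type), 42 (dcr1 deletion) and 122 (epe1 deletion). Enriched Mmi1 target genes numbered 0 (sir2 deletion). Enriched other island genes numbered 1 (dcr1 deletion) and 0 (epe1 deletion). The other island median level was 0.48 (epe1 deletion). The other island median difference was -0.63 (epe1 deletion). Enriched mating and nitrogen genes numbered 0 (wild type) and 2 (epe1 deletion). Enriched phosphate genes numbered 0 (wild type) and 1 (epe1 deletion). The tlh1 levels were 5.95 (wild type), 6.86 (dcr1 deletion), 1.87 (sir2 deletion) and 0.60 (epe1 deletion). Enriched tlh1 numbered 0 (epe1 deletion). The tlh1 differences were 0.78 (dcr1 deletion), -4.22 (sir2 deletion), -5.35 (epe1 deletion) and 5.09 (dcr1 against sir2 deletion). Enriched Tf2 elements numbered 0 (wild type), 0 (dcr1 deletion), 0 (sir2 deletion) and 0 (epe1 deletion). The Tf2 median levels were -3.53 (wild type), -3.39 (dcr1 deletion), -0.25 (sir2 deletion) and -6.26 (epe1 deletion). The Tf2 median differences were 0.32 (dcr1 deletion), 3.29 (sir2 deletion), -2.69 (epe1 deletion) and -3.12 (dcr1 against sir2 deletion). The wtf median levels were -1.61 (wild type), -1.37 (dcr1 deletion), -0.057 (sir2 deletion) and -3.06 (epe1 deletion). The wtf median differences were 1.56 (sir2 deletion), -1.53 (epe1 deletion) and -1.30 (dcr1 against sir2 deletion). Enriched housekeeping genes numbered 1 (wild type) and 0 (dcr1 deletion). Gene differences (epe1 deletion) were -1.20 at ssm4, -0.41 at num1, -1.02 at mcp7 and -0.56 at mbx2. Gene differences (dcr1 deletion) were 0.019 at SPAC8C9.04.

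With mode centring enriched other meiotic genes numbered 9 (starved). Enriched mating and nitrogen genes numbered 2 (wild type). The Tf2 median level was 1.72 (epe1 deletion).

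After mating-type scaling the pericentromere differences were 0.24 (sir2 deletion), 0.27 (epe1 deletion), -0.83 (starved) and -2.23 (dcr1 against sir2 deletion). The mating-type differences were 0.12 (dcr1 deletion), 0.14 (sir2 deletion), 0.040 (starved) and 0.066 (dcr1 against sir2 deletion). The subtelomere differences were 0.85 (dcr1 deletion) and -0.23 (starved). The chromosome III end difference was 0.056 (starved). Island counts were 135 (sir2 deletion). Enriched other meiotic genes numbered 1 (dcr1 deletion) and 2 (sir2 deletion). Enriched mating and nitrogen genes numbered 1 (dcr1 deletion). Enriched phosphate genes numbered 0 (starved). The tlh1 levels were 9.54 (dcr1 deletion), 4.48 (sir2 deletion), 8.69 (epe1 deletion) and 7.59 (starved). The tlh1 differences were 0.90 (dcr1 deletion), -4.53 (sir2 deletion), -0.12 (epe1 deletion), -1.18 (starved) and 5.30 (dcr1 against sir2 deletion). Enriched Tf2 elements numbered 4 (dcr1 deletion), 10 (sir2 deletion) and 3 (starved). The Tf2 median levels were 1.35 (sir2 deletion), 1.82 (epe1 deletion) and 0.92 (starved). The Tf2 median differences were -0.036 (dcr1 deletion), 0.35 (sir2 deletion), 0.88 (epe1 deletion), -0.037 (starved) and -0.37 (dcr1 against sir2 deletion). Enriched wtf genes numbered 9 (sir2 deletion). The wtf median level was 0.83 (sir2 deletion). The wtf median differences were 0.44 (sir2 deletion) and -0.35 (dcr1 against sir2 deletion). Enriched housekeeping genes numbered 1 (sir2 deletion). Gene differences (starved) were -1.20 at SPAC186.06 and -1.26 at SPAC212.08C. Gene differences (epe1 deletion) were 0.42 at mei4.

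At a threshold of 2 log2 island counts were 23 (wild type), 15 (dcr1 deletion), 6 (sir2 deletion), 52 (epe1 deletion) and 35 (starved). At 0.6 log2 island counts were 186 (wild type), 218 (dcr1 deletion), 138 (sir2 deletion), 525 (epe1 deletion) and 431 (starved). At 4 median absolute deviations island counts were 54 (wild type), 60 (dcr1 deletion), 40 (epe1 deletion) and 30 (starved). With 5 probes or more island counts were 37 (wild type), 29 (dcr1 deletion), 3 (sir2 deletion), 79 (epe1 deletion) and 51 (starved). Over 100 kb the subtelomere level was 4.45 (starved). With 500 bp added enriched Mmi1 target genes numbered 0 (sir2 deletion). Enriched Tf2 transposons numbered 10 (wild type), 8 (dcr1 deletion) and 0 (sir2 deletion). The Tf2 median levels were 1.21 (wild type), 1.21 (dcr1 deletion), 1.84 (epe1 deletion) and 1.46 (starved). The Tf2 median differences were -0.50 (sir2 deletion) and 0.44 (dcr1 against sir2 deletion). The wtf median difference was 0.020 (dcr1 against sir2 deletion). Gene differences (epe1 deletion) were 0.078 at mei4.

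Keeping outlier spots enriched mating and nitrogen genes numbered 2 (wild type). Enriched Tf2 transposons numbered 2 (wild type). Enriched wtf genes numbered 1 (dcr1 deletion). On probes with 1 match the pericentromere levels were 1.59 (dcr1 deletion) and 5.58 (starved). Enriched tlh1 numbered 0 (wild type), 0 (dcr1 deletion), 0 (sir2 deletion), 0 (epe1 deletion) and 0 (starved). Enriched Tf2 transposons numbered 0 (wild type), 0 (dcr1 deletion), 0 (sir2 deletion), 0 (epe1 deletion) and 0 (starved). This filter left no level for tlh1 or the Tf2 elements, so these counts of 0 were fixed by it and show no loss of enrichment. Without near copies the pericentromere levels were 4.61 (wild type), 1.29 (dcr1 deletion), 4.35 (epe1 deletion) and 5.25 (starved). Island counts were 72 (dcr1 deletion). Enriched tlh1 numbered 0 (wild type), 0 (dcr1 deletion), 0 (sir2 deletion), 0 (epe1 deletion) and 0 (starved). Enriched Tf2 transposons numbered 0 (wild type), 0 (dcr1 deletion), 0 (sir2 deletion), 0 (epe1 deletion) and 0 (starved). Here too no level was left for tlh1 or the Tf2 elements, so these counts of 0 were fixed by the filter. The wtf median levels were 0.012 (wild type), -0.025 (dcr1 deletion), -0.023 (sir2 deletion) and 0.10 (starved). The wtf median differences were -0.084 (dcr1 deletion) and -0.075 (sir2 deletion). In the ChIP channel the pericentromere difference was 0.48 (epe1 deletion). The central core difference was -0.46 (epe1 deletion). The chromosome III end differences were -1.51 (sir2 deletion) and 1.35 (dcr1 against sir2 deletion). The tlh1 differences were -2.71 (sir2 deletion), 0.51 (epe1 deletion) and 2.35 (dcr1 against sir2 deletion). The Tf2 median differences were 0.14 (dcr1 deletion), 0.016 (sir2 deletion) and 0.97 (epe1 deletion). The wtf median differences were 0.25 (epe1 deletion) and -0.020 (dcr1 against sir2 deletion). Gene differences (dcr1 deletion) were -0.079 at ftm5. Gene differences (epe1 deletion) were 0.48 at ura4, 0.36 at mae2, 0.29 at SPBPB21E7.09, 0.29 at SPAC212.08C, 0.14 at pdc102 and 0.29 at mei4. By running median island counts were 59 (wild type), 52 (dcr1 deletion), 9 (sir2 deletion) and 104 (starved). Beyond 100 kb island counts were 62 (wild type) and 97 (starved).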

Other observations

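Elevated H3K9me2 reached far beyond the centromeric repeats in wild type. From 20 to 50 kb outside the centromeres the mean was 0.97 ± 0.58 in wild type (553 probes), 1.24 ± 0.85 in the epe1 deletion and 1.59 ± 0.57 under starvation. In the dcr1 deletion it was 0.19 ± 0.47 and in the sir2 deletion 0.16 ± 0.37. From 50 to 100 kb it was 0.29 ± 0.38 in wild type, 0.35 ± 0.58 in the epe1 deletion and 0.64 ± 0.53 under starvation, and 0.03 in both the dcr1 and the sir2 deletion. These zones were chosen after values had been seen.

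The ends of chromosome III differed from each other. The left end stood at 5.09 ± 0.74 in wild type and 3.71 ± 0.59 in the epe1 deletion, and the right end at 2.46 ± 2.17 and 4.73 ± 1.23. From 30 to 40 kb at the left end the epe1 deletion stood at 3.72 ± 2.32, the dcr1 deletion at 1.07 ± 0.47 and wild type at 0.13 ± 0.49. Several islands that rest on 1 high probe recurred between arrays. The island at sof1 had a mean of 2.90 under starvation and 2.33 in the sir2 deletion, and that at sec59 and prp28 one of 2.73 in the dcr1 deletion and 2.14 in the sir2 deletion. Outside constitutive regions wild type correlated at 0.823 with the starved array, 0.774 with the dcr1 deletion, 0.607 with the epe1 deletion and 0.486 with the sir2 deletion.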
